A study of Homo sapiens with 4 samples.

How the data were processed

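RNA was extracted from A549 cells with a phenol and chloroform method, and polyadenylated RNA was isolated on oligo-dT beads and made into libraries with the Lexogen SENSE kit for mRNA sequencing, per the labels' protocols. The samples were 4 libraries, 2 of a PSME4 knockdown and 2 of a control knockdown, and groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, cutadapt, STAR and DESeq2 were used with the genome build hg38; versions, settings, the read counter, its strand setting and the gene annotation are not given in the sources used here.

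The deposited table held whole-number counts per gene for each library, with no normalisation, per the file headers. It also held deposited signal values, which equal the counts divided by 1 size factor per library, and the mean of these over all libraries. A further set of deposited values is on a log2 scale, per the file headers a regularised log, and was not tested here. The authors' own comparison was given as a log2 fold change of control KD over PSME4 KD, a p-value, an adjusted p-value that equals the Benjamini-Hochberg adjustment over all rows, and a further adjusted p-value by a method that is not stated. The largest count over the 4 libraries was at least 6 in each row, so the table had been filtered on low counts before it was deposited, by a rule that is not given in the sources used here. Such a filter removes genes near the detection limit and leaves fold changes of the kept genes as they were.

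The raw counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 13497 of 15037 genes, libraries were scaled by TMM, and glmQLFit and glmQLFTest were fitted to all 4 libraries with the group as the only term and 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM values are scaled by TMM, and SDs are over the 2 libraries of a group. Each library counted as 1 replicate, per the sample titles. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 23.9 between the control KD libraries and 19.1 between the PSME4 KD libraries, which does not show whether they came from separate cultures. The SD over genes of the log2 difference between libraries of a group was 0.35 in control KD and 0.28 in PSME4 KD, over 8748 genes with a mean of at least 10 CPM, and the biological coefficient of variation was 15.3%. The first principal component of log2 CPM held 61.3% of the variance and separated the groups, and the second held 24.1% and separated the control KD libraries. Depth was 11766371 to 15208588 counts per library, and the control KD libraries were the shallower ones. No batch is given in the labels.

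Before the data were examined, 28 gene lists with 731 genes were fixed, and 639 of the genes were in the table, 1 under an older symbol. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and also with an estimated correlation and with fry. The named genes follow a rule fixed at the same time: PSME4, then the 12 largest increases and 12 largest decreases among genes past the threshold whose libraries do not overlap between groups, with a mean of at least 5 CPM and a proper symbol, then up to 4 members of each list with the smallest p-values, with some class I and inducible proteasome genes named in any case. Some genes that this rule takes are not reported here, and counts over lists include them. The PDGFRA, CD68, CD14, ESAM and EGFL7 values come from the lists of other cell types, which had too few genes for a list test.

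Alternatives chosen before the data were examined were DESeq2's size factors, library size as the only scaling, DESeq2 1.42.0, limma voom, no filter on counts, a filter of at least 50 counts in 2 libraries, the replicate number as a block, each library left out in turn, a threshold of 0.10 and a test against a log2 change of 0.58. A correction for GC content, alone and with transcript length, was added after seeing the data. It subtracts from each library a lowess trend (span 0.4) of its log2 deviation on the GC content of the longest transcript of the gene in GENCODE 29, which 97.5% of the tested genes had, and enters edgeR as an offset. Coordinates and symbols were taken from RefSeq on GRCh38.p14, the same assembly as hg38; 14478 genes matched by symbol, 339 by an older symbol and 220 were not matched. Of the 128 named genes, 63 overlap another RefSeq gene, and since strand use in the counting is not stated, reads of overlapping genes may have been shared or dropped.

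The steps were tested on simulated data, drawn for 13497 genes from the means, library sizes and dispersions of this comparison, with 200 genes changed. Of 13320 genes run through edgeR, 63 of 66 genes changed 4-fold were recovered, 47 of 67 changed 2-fold and 5 of 67 changed 1.5-fold, with 0 false calls. With no gene changed, edgeR called 0 of 13309 genes. When 1 list, the ribosomal proteins, was raised by 0.5 on the log2 scale, camera called 1 of 24 lists, over 13317 genes. Simulated genes varied independently, while the estimated correlation of this list was 0.39 in the data. The simulation therefore does not show how small a list shift camera could find here. A simulated GC trend in control KD 2 gave a rho of 0.35 between fold change and GC content over 13320 genes, and 0.010 after the correction over 12999 genes. The trend was put in and removed by the same kind of lowess fit, so its removal was fixed in advance. With no gene changed the trend gave 0 calls. The simulated dispersions came from the real libraries, which already held this trend, so its spread was put in again. The 0 calls therefore do not show that the trend adds no calls in the data. Of 192 changed genes with a GC value, 105 were recovered after the correction. A simulated shift of chromosome 8 by −0.3 was recovered as −0.28 over 13003 genes.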

Results

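Messenger RNA was sequenced from A549, an established line of human lung carcinoma epithelial cells. The series asked which transcripts differ once the cells are depleted of PSME4, an activator that caps the proteasome core particle, and its title concerns tumour immunogenicity. There were 4 libraries, 2 from cells with a PSME4 knockdown (PSME4 KD) and 2 from control cells, whose knockdown the labels give as RFP (control KD). The count table covered 15037 genes, with 11766371 counts in control KD 1, 11769392 in control KD 2, 15208588 in PSME4 KD 1 and 14845701 in PSME4 KD 2. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. All fold changes are PSME4 KD over control KD with 2 libraries in each group. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13497 genes, unless another test is named.

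PSME4 mRNA fell 2.11-fold in the PSME4 KD libraries. It stood at 158 and 180 CPM (counts scaled to the size of the library) in control KD 1 and 2, and at 75.3 and 85.1 CPM in PSME4 KD 1 and 2. The log2 fold change was −1.08 (SE 0.20), with an adjusted p of 0.000855 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, from 3921 counts in the control KD libraries and 2444 in the PSME4 KD libraries. The gene spans positions 53864069 to 53970993 of chromosome 2 on GRCh38. In edgeR fits with 1 library left out, the adjusted p was 0.0522 without control KD 1, 0.0599 without control KD 2, 0.146 without PSME4 KD 1 and 0.0145 without PSME4 KD 2, while the log2 fold change stayed between −1.17 and −0.97. Tested against a log2 change of 0.58 it did not pass (adjusted p = 0.118, edgeR).

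The transcripts that fell most in PSME4 KD cells were those of EPHA7, an ephrin receptor tyrosine kinase, and PXDN, a peroxidase of the extracellular matrix. EPHA7 went from 20.4 ± 2.41 CPM (SD, n = 2) to 0.492 ± 0.139 CPM, a log2 fold change of −5.35 (SE 0.36). PXDN went from 19.6 ± 0.0367 CPM (SD, n = 2) to 0.525 ± 0.000376 CPM, a log2 fold change of −5.20 (SE 0.35), although only 16 PXDN counts and 15 EPHA7 counts remained in the PSME4 KD libraries. The transcripts that rose most were GRIK2, a kainate-type glutamate receptor subunit, from 1.51 ± 0.298 CPM (SD, n = 2) to 29.3 ± 0.907 CPM, and ANXA10, an annexin, from 1.29 ± 0.494 CPM to 16.6 ± 2.66 CPM. Their log2 fold changes were 4.27 (SE 0.30) and 3.67 (SE 0.34).

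Among the other large decreases, neurotensin (NTS) fell by 3.06 on the log2 scale (SE 0.25), the cadherin CDH19 by 2.77 (SE 0.35), the serpin SERPINB4 by 2.53 (SE 0.33) and SLFN11, a protein that sensitises cells to DNA damage, by 2.51 (SE 0.26). The uroplakin UPK1B fell by 2.46 (SE 0.30), the chemokine receptor CXCR4 by 2.46 (SE 0.33), the proteoglycan SDC2 by 2.36 (SE 0.28) and the neurofilament subunit NEFL by 2.30 (SE 0.23). The RNA polymerase III transcripts RN7SK and RMRP, which lack a poly(A) tail, fell by 2.67 (SE 0.41) and 2.43 (SE 0.38). RN7SK also differed between the control KD libraries, at 23.3 and 7.31 CPM, as did RMRP, at 30.6 and 12.4 CPM, and neither passed the threshold by DESeq2. In edgeR fits with 1 library left out, RN7SK was at −1.61 without control KD 1 and −2.16 without PSME4 KD 1, past no threshold in either. RMRP lost its call without control KD 1 (−1.64), control KD 2 (−2.94) and PSME4 KD 1 (−1.80). Both SDC2 and NEFL lie on chromosome 8, where the median log2 fold change of the 477 tested genes was −0.35. SERPINB4 has a near-identical neighbour in SERPINB3, so its counts are uncertain.

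Among the other large increases, OLFML3, a secreted glycoprotein, rose by 2.60 on the log2 scale (SE 0.28), the glycosyltransferase-like gene GALNTL6 by 2.51 (SE 0.32) and the hyaluronan receptor LAYN by 2.42 (SE 0.34). The trypsinogen PRSS3 rose by 2.20 (SE 0.31) and the metallothionein MT1F by 2.20 (SE 0.32), both with close paralogs that can share reads. ACKR3, an atypical receptor for the ligand of CXCR4, rose by 2.17 (SE 0.26), and PPARGC1A, a transcriptional coactivator of mitochondrial genes, rose by 1.75 (SE 0.27). The glucuronosyltransferase genes UGT1A6, UGT1A9 and UGT1A1 rose by 2.28 (SE 0.28), 1.78 (SE 0.22) and 1.73 (SE 0.27), but they share exons at 1 locus, so the counts cannot be assigned to one of them with certainty. The adjusted p-values of these 24 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were between 4.26e-11 and 0.000154.

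**Figure D1:**
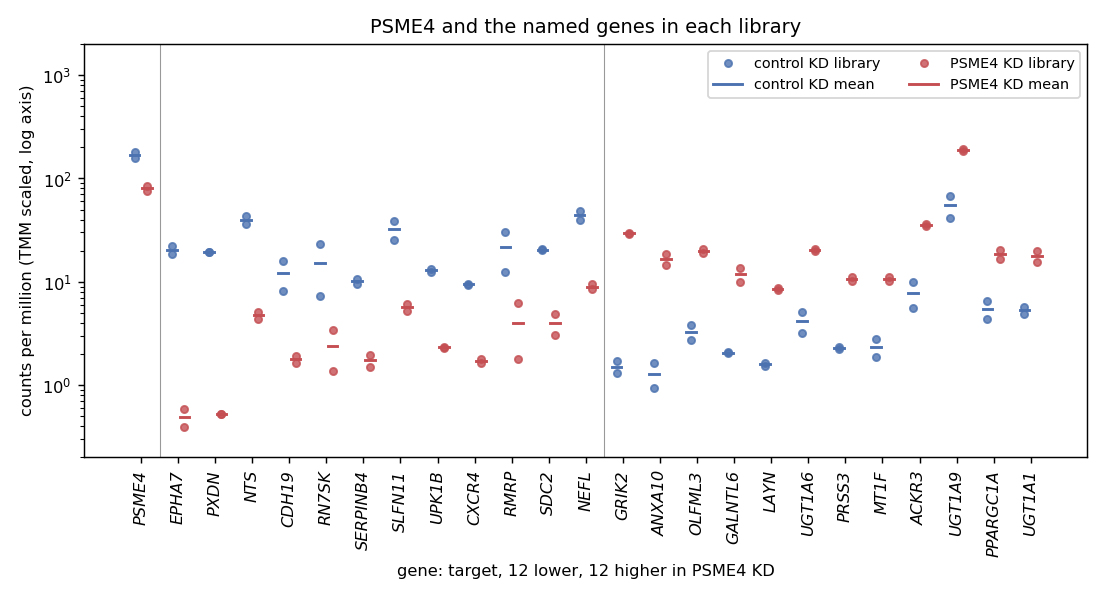
CPM (TMM scaled, log axis) of PSME4, the 12 genes with the largest decreases and the 12 with the largest increases; each point is 1 library and each bar the mean of 2 libraries, blue for control KD and red for PSME4 KD. PSME4 lies at 158 and 180 CPM in control KD and at 75.3 and 85.1 CPM in PSME4 KD, and in each of the other 24 genes the libraries of the 2 groups do not overlap.

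In all, 1426 genes changed, 616 higher and 810 lower in PSME4 KD cells, and 504 of them changed at least 2-fold (230 higher and 274 lower). Which direction held more genes depended on the scaling, as library size alone gave 853 higher and 764 lower, and on the libraries, as the fit without PSME4 KD 2 gave 192 higher and 89 lower. At an unadjusted p under 0.05 there were 3530 genes. The libraries of the 2 groups did not overlap in 55.0% of the genes tested, where the average over all splits of the libraries into pairs is 33.3%. Since genes do not vary independently, these shares are a description and not a test. With 1 library left out, edgeR called 53 genes without control KD 1, 94 without control KD 2, 43 without PSME4 KD 1 and 281 without PSME4 KD 2, and of the 24 genes with the largest changes it called 20, 21, 20 and 24 in the same direction. Most of the 1426 calls were lost in each of these smaller fits, so the loss of a call in the lists below was the usual outcome. Over all tested genes 10.6% passed, a share to set beside the counts in these lists. The lists also differed in expression, and genes with few counts are harder to call. The median control KD value was 1090 CPM for ribosomal proteins and 195 for proteasome subunits. It was 24.4 CPM for MHC class I genes and 10.4 for type I interferon genes. Tested against a change of 0.58 on the log2 scale (about 1.5-fold), 115 genes passed, 43 higher and 72 lower.

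Fold changes followed the GC content of the transcripts, as did the difference between the control KD libraries. Across 13154 genes, which are not independent replicates, Spearman's rho with GC content was 0.40 for the fold change, −0.49 for control KD 2 over control KD 1 and 0.098 for PSME4 KD 2 over PSME4 KD 1. For PSME4 KD 1 and 2 it was 0.13 and 0.17 over control KD 1, and 0.54 and 0.54 over control KD 2, so control KD 2 carried most of the 0.40. In the decile of genes with the lowest GC content 10 genes rose and 187 fell, and in the decile with the highest 94 rose and 32 fell. A correction of each library for GC content, chosen after seeing the data, gave 1230 genes, 540 higher and 690 lower, and kept 899 of the 1426 calls in the same direction. All 24 genes with the largest changes remained called after it.

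**Figure D2:**
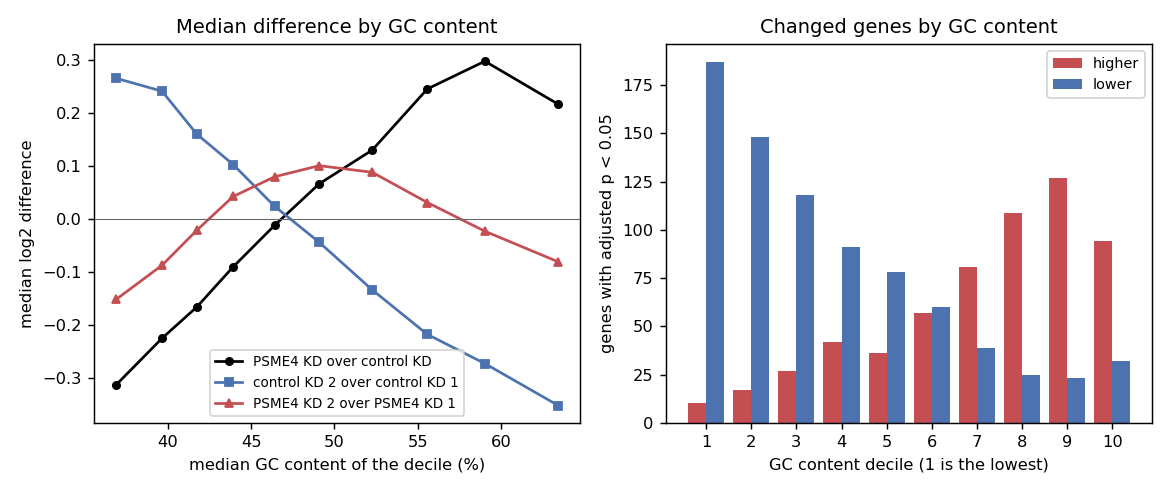
Left, the median log2 difference in each decile of genes by GC content, against the median GC content of that decile (%), for PSME4 KD over control KD (black), control KD 2 over control KD 1 (blue) and PSME4 KD 2 over PSME4 KD 1 (red); right, the number of genes past an adjusted p of 0.05 in each decile, higher (red) and lower (blue) in PSME4 KD. The black line goes from −0.31 in the lowest decile to 0.22 in the highest, and the blue line from 0.26 to −0.35.

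Genes of the proteasome itself moved in both directions. Of 33 tested subunits of the core and regulatory particles, 3 rose, 6 fell and 24 did not pass the test, and adjusted over the list alone the counts were 4 and 7. After the GC correction 1 was higher and 3 were lower. PSMD8, a lid subunit, rose (log2 fold change 0.97, SE 0.19), while the base subunit PSMD1 (−0.89, SE 0.21) and the core subunits PSMA4 (−0.80, SE 0.20) and PSMA3 (−0.66, SE 0.20) fell. The call of PSMA3 ended after the GC correction (−0.38, adjusted p = 0.206 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among 17 immunoproteasome subunits and other proteasome regulators, 2 fell and none rose, by either adjustment, over all genes or adjusted over the list alone. These were the assembly chaperones POMP (−1.05, SE 0.20) and PSMG1 (−0.65, SE 0.21), while PSMG4, another one, had a value of −0.65 (SE 0.24, and −0.41 without control KD 1) that did not pass. The inducible subunits PSMB8, PSMB9 and PSMB10 had log2 values of 0.52 (SE 0.26), 0.11 (SE 0.32) and 0.43 (SE 0.35), and the other proteasome activators PSME1, PSME2 and PSME3 had 0.42 (SE 0.21), 0.20 (SE 0.19) and −0.03 (SE 0.19), none past the threshold. Without control KD 1 PSMB9 was at 0.72 and PSME1 at 0.69, without control KD 2 PSMB9 was at −0.31, PSMB10 at 0.25 and PSME1 at 0.19, and without PSME4 KD 1 and 2 PSME2 was at 0.34 and 0.09. Of the 11 genes of both lists that passed, edgeR called 0, 1, 0 and 1 in fits without control KD 1, control KD 2, PSME4 KD 1 and PSME4 KD 2, with PSMD1 at −0.57 without control KD 1.

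Of 17 tested genes of MHC class I antigen presentation, none passed by edgeR, limma voom or DESeq2, and 1 had an unadjusted p under 0.05 by edgeR. This was HLA-F at 1.21 (SE 0.47, adjusted p = 0.0940 by edgeR with Benjamini-Hochberg adjustment), from 20 counts in control KD and 61 in PSME4 KD. The class I heavy chains HLA-B and HLA-C had log2 values of −0.06 (SE 0.25) and 0.22 (SE 0.25), uncertain because these genes share reads. The light chain B2M was at −0.17 (SE 0.20), the peptide transporter TAP1 at 0.40 (SE 0.24), the class I transactivator NLRC5 at 0.78 (SE 0.43) and the chaperone PDIA3 at −0.34 (SE 0.19). HLA-B and HLA-C had 13.9 and 12.7 CPM on average in control KD. After the GC correction HLA-B was at −0.29, HLA-C at 0.0048, TAP1 at 0.17 and NLRC5 at 0.54, and 0 of the 17 genes passed. Without control KD 1 HLA-B was at 0.18, HLA-C at 0.46 and PDIA3 at −0.18, without control KD 2 HLA-B was at −0.25 and HLA-C at 0.02, and without PSME4 KD 2 B2M was at −0.35.

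Among 34 type I interferon-stimulated genes, LGALS3BP, a secreted lectin ligand, rose (0.64, SE 0.20) and SAMD9, an antiviral factor, fell (−0.98, SE 0.29). Adjusted over the list alone neither passed, and neither did after the GC correction (0.41 and −0.64) or in any of the edgeR fits with 1 library left out (0 of 2), with SAMD9 at −0.45 without control KD 2. SAMD9L and IFIT1 had values of −0.81 (SE 0.29) and −0.51 (SE 0.23) that did not pass. None of 15 genes of the interferon-gamma response and MHC class II passed by edgeR, limma voom or DESeq2, and 4 had an unadjusted p under 0.05 by edgeR. These were the kinase JAK2 (−0.65, SE 0.22), APOL1 (−0.87, SE 0.32), the GTPase GBP1 (0.74, SE 0.32) and the transcription factor IRF1 (0.60, SE 0.28). IRF1 was at 0.93 without control KD 1 and 0.33 without control KD 2, and IFIT1 at −0.32 without PSME4 KD 2.

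Of 26 tested NF-kB targets, chemokines and cytokines 4 fell and none rose, with the same counts when adjusted over the list alone. After the GC correction 1 was higher and 4 were lower. CXCL8, which encodes a neutrophil chemoattractant, fell from 40.6 ± 2.75 CPM (SD, n = 2) to 9.95 ± 3.30 CPM, a log2 fold change of −2.03 (SE 0.25). IL11 (−1.13, SE 0.23), the apoptosis inhibitor BIRC3 (−1.03, SE 0.22, and −0.67 after the GC correction) and the chemokine CXCL2 (−0.91, SE 0.24) also fell. CXCL8 kept its call without any one library. In these smaller fits BIRC3 stayed between −1.15 and −0.90 and CXCL2 between −1.24 and −0.61, but neither passed without any one library (smallest adjusted p 0.0752 and 0.123, edgeR with Benjamini-Hochberg adjustment). IL11 lost its call without control KD 1 (−0.92), control KD 2 (−1.31) or PSME4 KD 1 (−0.98). Among 17 immune checkpoint ligands, CEACAM1 rose (1.47, SE 0.24) and ULBP3, a ligand of an activating natural killer receptor, fell (−0.90, SE 0.27), by both adjustments, over all genes and adjusted over the list alone. NECTIN2 and TNFSF9 were at 0.53 (SE 0.20) and −0.52 (SE 0.24) and did not pass, and TNFSF9 was at −0.21 without control KD 1. After the GC correction NECTIN2 was at 0.29 and TNFSF9 at −0.74. Of the 6 genes of both lists that passed, edgeR called 1, 2, 1 and 3 in fits without control KD 1, control KD 2, PSME4 KD 1 and PSME4 KD 2.

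Cell cycle genes moved both ways. Among 32 genes of G2/M and mitosis 5 rose and 3 fell, and adjusted over the list alone 5 and 5. The mitotic kinase PLK1 (0.77, SE 0.21) and the transcription factor FOXM1 (0.67, SE 0.21) rose, while HMMR (−0.99, SE 0.20) and the kinase CDK1 (−0.68, SE 0.20) fell. After the GC correction 1 gene of this list was higher and 1 lower, and PLK1 (0.53), FOXM1 (0.46) and CDK1 (−0.38) no longer passed. Of 31 genes of G1/S and DNA replication, CDC6, which licenses replication origins, fell (−0.69, SE 0.19), and this 1 decrease also held adjusted over the list alone. The replication genes POLE2 (−0.58, SE 0.20), RFC4 (−0.55, SE 0.20) and GINS1 (−0.51, SE 0.20) did not pass. Of 26 p53 targets, the nuclease AEN rose (0.84, SE 0.22) and 4 fell, 5 adjusted over the list alone, among them TRIAP1 (−0.78, SE 0.20), the ribonucleotide reductase subunit RRM2B (−0.73, SE 0.21) and TP53I3 (−0.66, SE 0.21). RRM2B, a chromosome 8 gene, lost its call after the GC correction (−0.41) and was at −0.46 without control KD 2. None of the 14 genes of these lists that passed did so in an edgeR fit with any 1 library left out.

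Junction and matrix genes included large changes in opposite directions. Of 16 epithelial and keratin genes 2 rose and 1 fell, with the same counts adjusted over the list alone. The claudin CLDN2 rose from 240 ± 57.6 CPM (SD, n = 2) to 570 ± 68.2 CPM (log2 fold change 1.25, SE 0.21) and the claudin CLDN1 fell from 189 ± 10.9 CPM to 80.0 ± 10.7 CPM (−1.24, SE 0.20). JUP, a desmosome protein, rose by 0.62 (SE 0.20) but did not pass after the GC correction (0.38), and PKP3 had a value of 0.73 (SE 0.36) that did not pass and ranged from 0.18 without PSME4 KD 1 to 1.23 without control KD 1. Of 28 mesenchymal and matrix genes 3 rose and 4 fell, also adjusted over the list alone. The basement membrane collagen COL4A1 (−1.86, SE 0.21) and the serpin SERPINE2 (−0.93, SE 0.19) fell, and N-cadherin (CDH2, 1.01, SE 0.21) and TAGLN, an actin-binding protein (1.45, SE 0.32), rose. Among 23 TGF-beta and YAP targets 2 rose and 2 fell, 4 and 2 adjusted over the list alone. The growth factor BMP4 (1.69, SE 0.24) and the inhibitor of differentiation ID2 (1.09, SE 0.21) rose, while the receptor kinase AXL (−0.83, SE 0.22) and AMOTL1 (−0.66, SE 0.22) fell, AMOTL1 neither with library size as the only scaling nor by DESeq2. Of 5 alveolar and airway epithelial markers that could be tested, TP63 (1.29, SE 0.24), a basal cell transcription factor, and MUC5AC (1.08, SE 0.26), a secreted mucin, rose, also adjusted over the list alone, and ABCA3 (0.50, SE 0.28) and SOX2 (−0.47, SE 0.41) did not pass. ABCA3 was at 0.82 without control KD 1 and 0.24 without control KD 2, and SOX2 at −0.89 without PSME4 KD 1 and −0.12 without PSME4 KD 2. Of the 16 genes of these lists that passed, edgeR called 2, 5, 1 and 8 in fits without control KD 1, control KD 2, PSME4 KD 1 and PSME4 KD 2, with AXL at −0.42 without control KD 1 and MUC5AC at 0.56 without PSME4 KD 2.

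Of 20 heat shock genes and cytosolic chaperones 3 fell and none rose, also adjusted over the list alone. The mitochondrial co-chaperonin HSPE1 fell by 1.52 on the log2 scale (SE 0.26), HSP90AA1 by 0.86 (SE 0.22) and DNAJA1 by 0.67 (SE 0.20), DNAJA1 not after the GC correction (−0.51). SERPINH1 had a value of 0.55 (SE 0.21) that did not pass. HSPE1 overlaps a read-through gene and HSP90AA1 has processed copies, so both are uncertain. Of 19 genes of the endoplasmic reticulum unfolded protein response 1 rose and 3 fell, 2 and 4 adjusted over the list alone. DNAJB9 (−0.97, SE 0.21), DERL1 on chromosome 8 (−0.85, SE 0.19) and the disulfide isomerase PDIA6 (−0.79, SE 0.21) fell, and CREB3L2 (0.61, SE 0.20) rose. Of 23 genes of the ATF4 and integrated stress response, NUPR1 rose (0.90, SE 0.29) and STC2 fell (−0.86, SE 0.23), also adjusted over the list alone, while ATF3 (−0.79, SE 0.30) and the amino acid transporter SLC7A5 (0.48, SE 0.19) did not pass. The call of NUPR1 ended after the GC correction (0.82). Of the 9 genes of these lists that passed, edgeR called 0, 0, 1 and 1 in fits without control KD 1, control KD 2, PSME4 KD 1 and PSME4 KD 2, with PDIA6 at −0.52 without control KD 1 and HSP90AA1 at −0.57 without PSME4 KD 2.

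Of 32 NRF2 targets 2 rose and 1 fell, 3 and 2 adjusted over the list alone. The pentose phosphate enzyme TKT (0.96, SE 0.20) and TRIM16L (0.67, SE 0.20) rose and PIR (−1.15, SE 0.24) fell, while the epoxide hydrolase EPHX1 (0.59, SE 0.20, and 0.38 without control KD 2) did not pass. Of 28 genes of hypoxia and glycolysis the hexokinase HK1 (0.73, SE 0.21) and the aldolase ALDOA (0.87, SE 0.29) rose and EGLN1, an oxygen sensor, fell (−0.61, SE 0.19), also adjusted over the list alone, and PGK1 (0.54, SE 0.20) did not pass. ALDOA had only 124 and 299 counts in the control KD and PSME4 KD libraries and overlaps another gene model, and both ALDOA (0.70) and EGLN1 (−0.53) kept most of their fold change after the GC correction but narrowly lost their calls (adjusted p 0.0784 and 0.0532, edgeR with Benjamini-Hochberg adjustment). Of 25 genes of cholesterol biosynthesis and SREBP2 targets 3 fell and none rose, also adjusted over the list alone. These were the synthase HMGCS1 (−0.97, SE 0.21), the epoxidase SQLE on chromosome 8 (−0.74, SE 0.19) and IDI1 (−0.70, SE 0.21, and −0.52 after the GC correction, where it did not pass). MSMO1 did not pass at −0.48 (SE 0.19, and −0.22 after the GC correction). Of 16 genes of fatty acid synthesis none passed by edgeR, 1 did by DESeq2 and 1 by limma voom, and 2 had an unadjusted p under 0.05 by edgeR. These were ACSL3 (−0.57, SE 0.19) and FASN (−0.67, SE 0.23, and −0.25 without control KD 1), while the desaturase SCD and ACLY were at −0.34 (SE 0.20) and 0.27 (SE 0.19), SCD at −0.21 without control KD 1. After the GC correction ACSL3 was at −0.31 and FASN at −0.84. Of the 9 genes of these lists that passed, edgeR called 0, 1, 0 and 2 in the fits without control KD 1, control KD 2, PSME4 KD 1 and PSME4 KD 2, with PIR at −0.72 without control KD 1 and IDI1 at −0.45 without PSME4 KD 2.

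Of 77 cytosolic ribosomal protein genes 13 rose and 6 fell, 21 and 8 adjusted over the list alone. RPS9 (0.98, SE 0.19) and RPS28 (1.01, SE 0.24) rose, and RPL9 (−1.20, SE 0.22) and RPS24 (−1.02, SE 0.21) fell. Within this list the fold change followed GC content with a Spearman's rho of 0.51 across genes, and after the GC correction 8 rose and 4 fell, and RPS28 (0.72) was no longer called. These genes have many processed pseudogenes, so single values are uncertain. Of 31 nuclear-encoded genes of oxidative phosphorylation 4 rose and 2 fell, 5 and 2 adjusted over the list alone. The cytochrome oxidase subunits COX4I1 (0.86, SE 0.21) and COX6C (−1.04, SE 0.21) went opposite ways, CYC1 rose (0.82, SE 0.22, and 0.57 after the GC correction, where it did not pass) and NDUFB3 fell (−0.73, SE 0.20). COX6C and CYC1 both lie on chromosome 8, CYC1 in its part from 130 Mb, where the median after the GC correction was −0.034. Of 19 histone genes 2 rose and 2 fell, also adjusted over the list alone, with H2AJ (0.83, SE 0.24) and H1-10 (0.75, SE 0.24) higher and H3-3B (−0.86, SE 0.19) among the lower ones. H1-10 lost its call after the GC correction (0.55). Of the 29 genes of these lists that passed, edgeR called 0, 3, 0 and 13 in fits without control KD 1, control KD 2, PSME4 KD 1 and PSME4 KD 2. RPL9 was at −0.77 without control KD 1, and RPS28, COX4I1 and CYC1 were at 0.54, 0.53 and 0.36 without PSME4 KD 1.

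Markers of other cell types were sparse. Of the fibroblast markers 4 could be tested and PDGFRA fell (−1.34, SE 0.43), from 2.60 and 2.58 CPM in control KD to 0.723 and 1.31 CPM in PSME4 KD, also adjusted over the list alone, but not by DESeq2, after the GC correction (−1.21) or in an edgeR fit with any 1 library left out. Another fibroblast marker, LUM, did not pass (0.54, SE 0.30) but was called higher after the GC correction (0.88). The immune markers CD68 (0.33, SE 0.22) and CD14 (0.37, SE 0.30) and the endothelial markers ESAM (−0.18, SE 0.26) and EGFL7 (−0.16, SE 0.35) did not pass by edgeR, limma voom or DESeq2, and none of the 4 had an unadjusted p under 0.05. The table had no row for the mitochondrially encoded mRNAs, which were not analysed here.

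None of the 24 lists with at least 5 tested genes stood apart from the other genes as a whole. With limma's camera test and a preset correlation, 0 lists passed, the smallest adjusted p was 0.525, and 1 list, the ribosomal proteins, had an unadjusted p under 0.05 (0.0478, direction up, and 0.123 after the GC correction). With an estimated correlation 0 lists passed and 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.888. The fry test for a shift in one direction passed 0 lists, and the fry test for changes in either direction passed 19. Unadjusted p by fry for one direction was 0.0203 for type I interferon genes and 0.0236 for p53 targets. It was 0.0244 for MHC class I genes and 0.0461 for the alveolar and airway markers. The smallest adjusted p was 0.195. Fry does not compare a list with the other genes, so its 19 lists do not show lists that stand apart. Median, mean and camera direction differed in sign for the proteasome regulators (median 0.0057, mean −0.076, down), checkpoint ligands (−0.083, 0.0067, down), mesenchymal genes (0.046, −0.063, down), fatty acid genes (0.0069, −0.086, down) and histones (−0.12, 0.013, up). Without PSME4 KD 2 the ribosomal protein list passed (adjusted p = 0.0294, camera with the preset correlation, direction up), a call not tested with an estimated correlation, which was 0.39 for this list with all libraries. Of the 96 changed members of these lists edgeR called 3 in the same direction without control KD 1, 12 without control KD 2, 3 without PSME4 KD 1 and 28 without PSME4 KD 2. Among the genes named above, DESeq2 did not call RN7SK, RMRP, PSMG1, SAMD9, ULBP3, AMOTL1, NUPR1, HSPE1, ALDOA, H1-10 and RPS28. Limma voom, and edgeR without a filter on counts, did not call JUP and CREB3L2, and edgeR with library size as the only scaling did not call PSMG1 and AMOTL1. After the GC correction PSMG4, TNFSF9, APOL1, FASN and PGK1 passed as well. By camera with the preset correlation 0 lists passed after it, and 2 had an unadjusted p under 0.05. These were the heat shock genes (0.0300, median −0.21) and the NF-kB targets (0.0391, median −0.15).

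**Figure D3:**
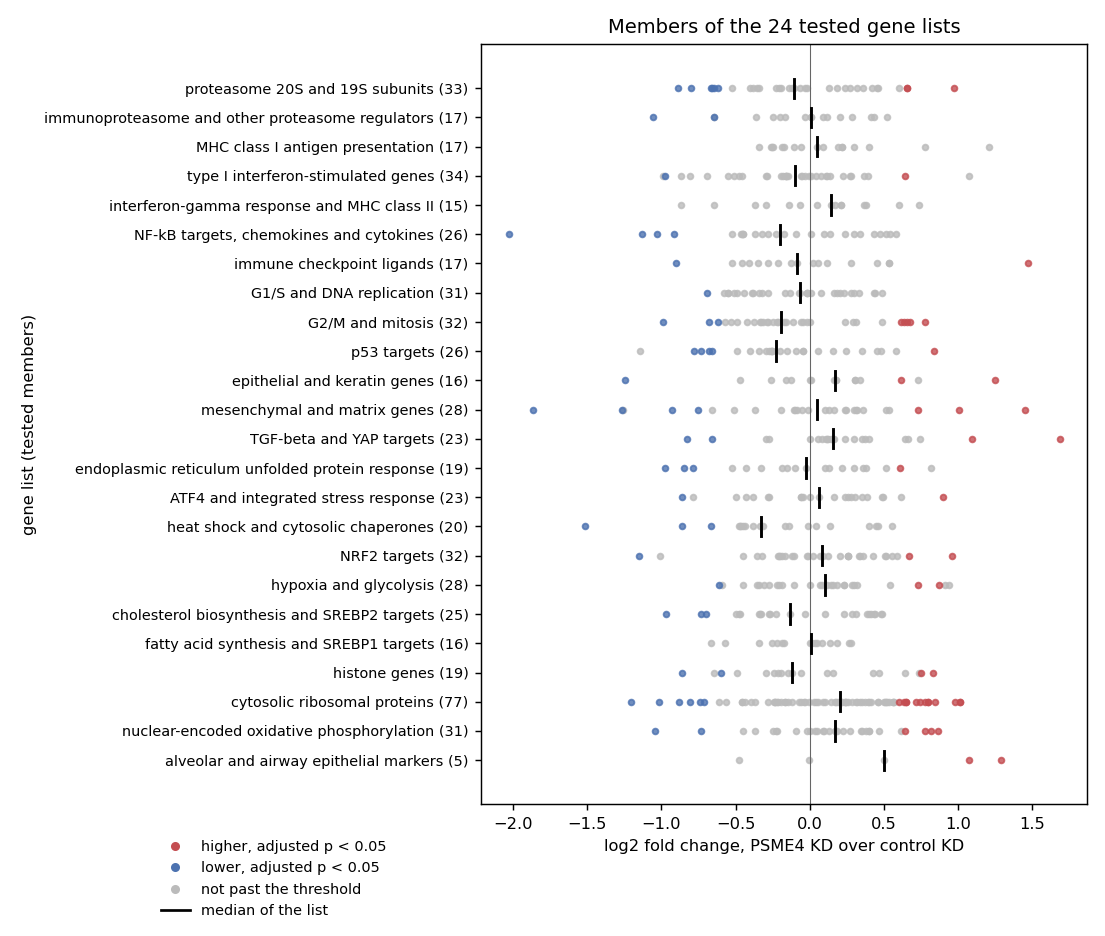
Log2 fold change (PSME4 KD over control KD) of each tested member of the 24 gene lists, with the number of tested members in brackets; each point is 1 gene, red where it passed as higher, blue where it passed as lower and grey where it did not pass, and the black bar is the median of the list. CXCL8 at −2.03 and COL4A1 at −1.86 are the lowest points, BMP4 at 1.69 is the highest, and the largest list median is 0.50, over the 5 alveolar and airway markers.

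In the authors' deposited table, 972 genes had an adjusted p under 0.05, 418 of them higher and 554 lower in PSME4 KD. Of these 972 genes, 958 were also called by edgeR in the same direction. A further 468 genes called by edgeR had no authors' adjusted p under 0.05. The authors' deposited table marks 316 genes as passing, 148 higher and 168 lower, each with a log2 change of at least 1.00 in size, and 94 genes after a further correction whose method is not stated. PSME4 has a log2 value of 1.07 as control KD over PSME4 KD in the authors' deposited table, with an adjusted p of 1.23e-05, and of 0.0203 after the further correction.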

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

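The GC corrections were chosen after seeing the data. The count of changed genes (1426) stayed within 1.5 times under DESeq2's size factors, library size, DESeq2, voom, both filters and both GC corrections, between 1129 and 1617. The balance turned with library size as the only scaling (853 higher, 764 lower) and without PSME4 KD 2 (192 higher, 89 lower), and more genes were lower in each other setting. At a threshold of 0.10 it was 2240 (1006 higher, 1234 lower), and against a log2 change of 0.58 it was 115 (43 higher, 72 lower). With fewer libraries in the fit it fell to between 43 and 281 (15 to 192 higher, 26 to 89 lower), the lone library being assumed to vary like the other group. PSME4 lost its call without control KD 1, control KD 2 or PSME4 KD 1, with log2 values of −1.17, −0.97 and −0.99, and against a log2 change of 0.58 (−1.08, adjusted p 0.118), and kept it in the other settings run. Lists past the threshold by camera went from 0 to 1 without PSME4 KD 2 (range with 1 library left out 0 to 1) and were 0 in the other settings run, which leave out DESeq2 and the 0.10 threshold. Fry gave 0 for one direction and 19 for either direction. With the replicate block 1554 genes passed, 700 higher and 854 lower, 1399 of the 1426 calls among them, and PSME4 was at −1.07. The numbers do not pair the libraries here, since the labels tie them to nothing shared and 2 pairs deviated with a correlation of −0.018. Values near 0 turned sign. With 1 library left out PSMB9 ranged from −0.31 (without control KD 2) to 0.72, PSME3 from −0.099 to 0.061, B2M from −0.35 to 0.0075 and HLA-B from −0.30 to 0.18. PSME3 was 0.011 with library size only, 0.0032 without control KD 1 and 0.061 without PSME4 KD 1. HLA-B was 0.18 without control KD 1 and 0.17 without PSME4 KD 1. B2M was 0.0075 without PSME4 KD 1, 0.014 with the GC correction and 0.071 with GC and length. None of these passed in either direction, and the cause was not tested. Of the 90 named genes that passed, 74 kept their call with the GC correction, 72 with GC and length and 79 by DESeq2. The replicate block did not call JUP, AMOTL1 and CREB3L2. GC and length ended the calls of PSMG1 (−0.57), CREB3L2 (0.48) and MUC5AC (0.59), which GC alone kept. Leaving out list members named in another list was not run, since no gene is in more than 1 list, and the settings for normalised values were not run because the table held counts. Depth limits the genes with few counts, such as EPHA7 and PXDN in PSME4 KD. Of the 3 splits of the 4 libraries into pairs, the labelled one gave 1426 genes and the highest of the others 0, and 3 splits are too few for a share under 0.05, so 1 split as large is the smallest count possible.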

Other observations

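The tests of library composition, of strongly changed genes, of chromosome 8 dosage, of the end of its long arm and of histone mRNAs were chosen after the result was seen, as were the 12 genes of the next paragraph. Intervals in this section were taken over genes as if these were independent, and leave out the spread between libraries.

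Genes outside the lists also changed in both directions, and 12 of them are given here without a test of any theme. IGFBP1, a binding protein of insulin-like growth factors, had a log2 fold change of −2.22 (SE 0.23), and INHBB, an activin subunit, fell from 89.3 ± 14.7 CPM (SD, n = 2) to 26.5 ± 6.80 CPM (−1.75, SE 0.22). The growth factor TGFA (−1.34, SE 0.22), the fibrinogen chain FGG (−1.67, SE 0.21), the cyclin CCND1 (−1.22, SE 0.20) and the transcription factor JUN (−1.41, SE 0.26) also fell. Higher were RBP4, a retinol carrier (1.57, SE 0.22), CRIP1 (1.58, SE 0.22), the metallothionein MT1X (1.25, SE 0.22), the transcription factor ETS2 (1.28, SE 0.20), the hedgehog receptor PTCH1 (1.54, SE 0.31) and the collagen COL11A1 (1.19, SE 0.20). All 12 genes were also called by DESeq2 and after the GC correction. As they were picked after their values were seen, this is no further support. Of all 1426 calls DESeq2 kept 1064 and the GC correction 899. Of these 12, edgeR called 5 without control KD 1, 8 without control KD 2, 4 without PSME4 KD 1 and 11 without PSME4 KD 2.

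Fold changes followed the GC content of the transcripts. A library composition that varies with GC content may account for part of this, since the control KD libraries differed in the same way with no PSME4 knockdown between them (rho −0.49 for control KD 2 over control KD 1, across genes). As the whole cause of the calls this trend is argued against by the 63.0% of the 1426 genes that kept their call and direction after the correction. A response of GC-rich and GC-poor genes to PSME4 KD stays open. Its sign was the same in each of the 4 pairings of a PSME4 KD with a control KD library (rho 0.13 and 0.17 over control KD 1, 0.54 and 0.54 over control KD 2), but control KD 2 carried most of it, and control KD 2 over control KD 1 reached a larger size than the pairings with control KD 1.

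Genes of chromosome 8 were lower in PSME4 KD cells, with 6 higher and 99 lower among 477 tested genes. The GC trend is argued against, as the median log2 fold change after the correction was −0.26 (95% bootstrap interval −0.32 to −0.21), while the medians of other chromosomes lay between −0.043 and 0.11. A few strongly changed genes are argued against, as 74.1% of the genes were negative against 47.9% on the other chromosomes. With genes taken as independent, the exact 95% interval of 69.9% to 78.1% lies above the 60% that this explanation allowed. Its lower end just misses the 70% set against the explanation. A lower dosage of chromosome 8 could account for the shift. Medians were −0.28 on the short arm and −0.25 on the long arm, and −0.24 and −0.26 in PSME4 KD 1 and 2 over the control KD mean. The 81 tested genes from 130 Mb to the end of the long arm argue against a shift of the same size there. Their median was −0.034 (95% interval −0.17 to 0.0022), against −0.31 for the 396 tested genes below it. This boundary was chosen from the same data where medians lay near 0, so the interval cannot exclude a smaller shift. After the correction 30% of the genes from 130 to 140 Mb were negative, and 63.8% from 140 to 150 Mb. Medians after the correction leave out genes with no GC value, and 468 of the 477 genes had such a value. DNA was not measured, so whether the shift came with the knockdown or from cell populations that already differed is untested.

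RNA polymerase III transcripts and snoRNAs, short RNAs without a poly(A) tail, were lower in PSME4 KD cells, with medians of −1.69 over 6 transcripts, 3 of which fell (RN7SK, RMRP and RPPH1), and of −0.49 over 56 snoRNAs (95% bootstrap interval −0.67 to −0.29; 1 higher and 4 lower). The GC trend is argued against, as the 5 RNA polymerase III transcripts with a GC value had a median of −2.30 before the correction and −2.45 after it. A carry-over of all RNA without a poly(A) tail alike would also lower the 16 replication-dependent histone mRNAs, which mostly lack the tail. Their median was 0.17 (95% bootstrap interval −0.12 to 0.53). The counts do not show whether the histone reads came from forms with a tail, so this argues against it only if they did not. A carry-over of short RNAs that differs between libraries stays open, as the RNA polymerase III transcripts summed to 85.1 and 38.7 CPM in control KD 1 and 2 and to 13.7 and 28.3 CPM in PSME4 KD 1 and 2, while the snoRNA median of control KD 1 over control KD 2 was −0.19 (95% interval −0.36 to 0.11).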
